A study of Mus musculus with 8 samples.

How the data were processed

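Gene expression of single mouse macrophages was measured with the BD Rhapsody targeted assay, in which each cell's transcripts are tagged with a unique molecular identifier (UMI) and a panel of 500 genes is amplified. Per the labels, cells were marked with anti-CD45 hash tags, up to 12 tagged samples were loaded together on a cartridge, and macrophages were lifted with Accutase and sequenced on a NovaSeq. iMPDM cells are macrophages differentiated for 10 days in L929-conditioned medium from myeloid progenitors immortalised with HoxB4. The doses of P3CSK and of the lower LPS sample, the ages of the mice and their number are not given in the sources used here.

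The deposited values are counts. Per the file headers, the authors made them with the BD Targeted Multiplex Rhapsody Analysis Pipeline version 1.9, which reports molecules per gene and cell after its distribution-based correction of UMI errors (DBEC), so each value is a whole number of UMIs with no normalization. The genome build is mm10 per the submitters' processing notes, and the aligner is not given in the sources used here. The panel was amplified with 5 primer sets per the deposited gene names. The authors' deposited annotation assigns each tag of each library to a cell type, a ligand, a time and a replicate number, and all groups were taken from it. It lists 343584 cells in 16 libraries, of which the 8 libraries with count files used here were analysed, and the 191830 cells of the other 8 libraries were not used. The 8 count files hold 151754 barcodes. Those called with more than 1 tag or with none (14115) were left out, which leaves 137639 cells, and no further doublet caller was run. Multiplets made up 5.01% to 9.60% of barcodes per library. Library 13 holds 51264 barcodes, more than the number loaded per the labels. No column of another series was present.

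UMIs were summed per library, cell type, ligand and time, since cells are not replicates. For M0 cells the replicate is the library, and the 15 sums of untreated and 3 h cells entered 1 fit of edgeR's quasi-likelihood test with TMM factors and edgeR's default filter on low counts (481 genes tested, 7 residual degrees of freedom, biological coefficient of variation 0.854). The annotation gives M0 cells of libraries 12 and 13 the same replicate number and those of library 8 another, so these libraries may not be 3 separate replicates. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The library as a block was the alternative fit (4 residual degrees of freedom, coefficient of variation 0.333). The annotation names the library a batch. In 21 pairs of sums from 1 library the correlations of deviations from the ligand means had a median of 0.760 and a minimum of 0.380, so that sums of 1 library deviated together. These pairs are not independent, since the deviations of a ligand held by 2 libraries mirror each other, and correlations between libraries were not used for that reason. The library was taken to pair the sums, and the blocked values stand beside the main ones. The blocked fit was chosen as an alternative before the data were examined, as were the groups, the other tests, the gene lists and the rule for named genes, but the check of pairing and the calls came from the same run.

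For untreated M1 and M2 against M0 cells the plan was to run no test unless the annotation named replicates. It names 2 per group in library 3, so the same edgeR test was run on 6 sums (418 genes, 3 residual degrees of freedom, coefficient of variation 0.0940). Nothing says that these replicates are separate cultures, and p-values then measure only the spread between these samples, which may be technical. Their counts differed by more than the sampling noise of independent UMIs (chi-square per degree of freedom 7.32 to 13.6), as did those of the 2 tags of LPS cells in library 13 with 1 replicate number (7.78), so this cannot tell separate cultures from repeated samples of 1 culture. All other comparisons have 1 sum per group and are log2 ratios of CPM (counts divided by the total of their sum and scaled to a common total) with a prior count of 0.5 in each sum and 95% intervals of the ratio from the counts. Comparisons of old with low-fat cells are differences of such log2 ratios. Against a sum of 0 UMIs the ratio was computed against a floor of 3 counts over the sum and is given as a bound. Intervals and floors cover counting error only. Sums compared at 3 h or untreated ran from 50205 UMIs in 58 untreated high-fat cells to 19112681 UMIs in LPS cells of library 13, whose 2 tags were joined.

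Gene lists were written for early NF-kB targets (27 genes on the panel), late inflammatory cytokines (25), type I interferon response (18), interferon gamma and MHC (13), interleukin 4 and alternative activation (15), immediate-early genes (13), feedback regulators (13), oxidative stress and hypoxia (8), lipid and sterol genes (2), cell cycle (2), and the cell type markers of macrophage identity (5), large (2) and small (3) peritoneal macrophages, neutrophils (2), mast cells, eosinophils and basophils (1), dendritic cells (3), progenitors (1), and B cells, T and NK cells and stromal cells (0 on the panel each). A list's median over members with at least 10 UMIs was set against 10000 random lists matched on expression in 10 bins. Named genes in tested comparisons were the 8 largest rises and 5 largest falls past the thresholds in the same direction in every pair, and the 2 members with the smallest p of each list with at least 3 measured genes. In the others they were the 8 largest and 5 smallest log2 ratios at 50 or more UMIs and the 2 list members with the largest absolute ratio. Tnf, Il1b, Il6, Il12b, Cxcl10, Ifit1, Ccl5, Nfkbia, Arg1 and Nos2 were always named. Not every gene that the rule gives is printed or drawn. A cell counted as carrying markers of another type with at least 2 different markers of B, T or NK, neutrophil, mast or stromal cells. On the panel these markers were S100a8, Mmp8 and Ccr3. Positions are from the GENCODE vM21 annotation of the same build.

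For shares of cells and for assignment of cells to ligands each cell was thinned to 300 UMIs, the 10th percentile of 97508 cells (395) rounded down, and shallower cells were left out. Cells were assigned by multinomial logistic regression (penalty C of 0.1, counts scaled to 1000 UMIs, log1p, standardised genes) in 5 folds with equal numbers per ligand, with a random forest of 200 trees as alternative. The steps were tested on simulated data. With 481 genes the main M0 fit called 0% of 4-fold changes, and the blocked fit called 47% for LPS, 29% for PIC and P3CSK, 36% for CpG and 32% for TNF against untreated cells, and 88%, 83% and 85% for LPS against TNF, CpG and PIC. With 418 genes the polarization fit called 98% for M1 and 100% for M2. With ligand labels shuffled in library 8, 32.7% of cells were assigned to their ligand over 500 genes.

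The alternatives were library totals, DESeq2 size factors and counts per cell as scaling, no filter on low counts, the DESeq2 Wald test, cells of at least the thinning depth, each library or replicate left out, TMM factors and counts per cell for ratios, cells not thinned, and 2 UMIs in place of 1. Treating the 2 untreated M0 replicates as separate sums, blocking by annotated replicate number, and most settings of the polarization test were added after seeing the data. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.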

Results

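Mouse macrophages of 6 kinds were exposed to single immune ligands and profiled by single-cell RNA sequencing with a targeted panel of 500 genes on the BD Rhapsody platform. M0 macrophages were differentiated from HoxB4-immortalised myeloid progenitors (iMPDMs), M1 and M2 macrophages were the same cells kept for 24 h in 50 ng/mL interferon gamma or 50 ng/mL interleukin 4, and peritoneal macrophages came from mice annotated as low-fat diet, high-fat diet or old. The ligands were lipopolysaccharide (LPS, 100 ng/mL), poly(I:C) (PIC, 50 µg/mL), CpG oligonucleotide (100 nM), TNF (10 ng/mL), interferon beta (IFNb, 500 U/mL) and P3CSK, a lipopeptide known to act through TLR2, with a lower LPS dose (LPSlo) in 1 library. Each library was 1 cartridge of up to 12 hash-tagged samples. The 8 libraries held 137639 cells with 1 tag and between 18462841 and 60730927 UMIs each in those cells. Library 1 held 47823920 UMIs (M2 cells at 3 h and 5 h), library 3 18462841 (M2 cells at 1 h and untreated M0, M1 and M2 cells) and library 5 53009037 (M1 cells). The M0 libraries 8, 12 and 13 held 47407874, 60730927 and 38708080, and the peritoneal libraries 15 (diet) and 16 (old) held 26877089 and 27306426. Median UMIs per cell ran from 723 in library 13 to 3468 in library 12, and sums of 1 sample at 3 h or untreated from 50205 UMIs (58 untreated cells of the high-fat arm) upward. M0 cells at 3 h came from 3 libraries, of which libraries 12 and 13 share an annotated replicate number, and untreated M0 cells from libraries 3 and 13. Per the annotation, untreated M0, M1 and M2 cells were sampled at 0 h and untreated peritoneal cells at 3 h. Ratios of M0, M1 and M2 cells to untreated cells therefore hold the ligand and the time since 0 h together. Untreated M0, M1 and M2 cells of library 3 carried 2 annotated replicates each. All other groups had 1 library and no replicates, so their log2 ratios of CPM, counts scaled to a common total per sum, are given without a test, with 95% intervals that cover counting error only.

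Polarization with interferon gamma was asked first, in untreated cells. M1 cells held more RNA of genes known from the interferon gamma response. The guanylate-binding protein gene Gbp2b rose by 9.21 (log2 fold change; SE 0.18, adjusted p = 9.17e-10), the T cell chemokine Cxcl9 by 8.69 (SE 0.27), the serpins Serpina3g and Serpina3f by 8.09 each (SE 0.13), the surface receptor Slamf8 by 7.94 (SE 0.12), and the immunity-related GTPases Iigp1 and Tgtp1 by 7.71 (SE 0.17) and 7.15 (SE 0.10). Of the 12 measured members of the interferon gamma and MHC list, 12 rose, and of 17 type I interferon genes 16 rose, among them Tnfsf10 (5.07, SE 0.10), Ifit1 (4.57, SE 0.30), Cxcl10 (6.62, SE 0.19) and Ifi205 (2.56, SE 0.07). Ifnb1, the interferon beta gene, was at least 22.6-fold higher, with 76 UMIs in M1 cells and 0 in M0 cells. Inflammatory genes were mixed: 4 of 25 early NF-kB genes rose and 1 fell, with the prostaglandin synthase Ptgs2 up by 3.96 (SE 0.08) and the adhesion molecule Icam1 by 1.66 (SE 0.07), and 6 of 16 late cytokine genes rose and 1 fell, with the formyl peptide receptor Fpr2 (3.97, SE 0.14) and the lymphocyte activation marker Cd69 (2.70, SE 0.08) as the examples. Tnf (0.18, SE 0.08, adjusted p = 0.0762), Il1b (-1.24, SE 0.51, adjusted p = 0.0574), Nfkbia (-0.24) and Arg1 (0.17) did not pass.

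Among the genes lower in M1 cells, the glutathione transferase Gsta3 fell by 4.75 (SE 0.23), the scavenger receptor Marco by 4.38 (SE 1.13), the calcium pump Atp2b4 by 3.23, the intermediate filament gene Nes by 3.02 and the LPS co-receptor Cd14 by 2.02 (SE 0.07). Of 8 oxidative stress and hypoxia genes 6 fell and 0 rose, among them the heme oxygenase Hmox1 (-1.29, SE 0.07) and the metallothionein Mt1 (-1.11, SE 0.07). Among immediate-early genes 2 of 12 rose (Egr3 by 2.07) and 1 fell (Fosb, -2.03), and among feedback regulators 1 of 11 rose (the cytokine signalling inhibitor Socs3, 2.43) and 2 fell (the phosphatase gene Dusp4, -1.70). Of 13 genes of alternative activation 2 rose and 1 fell, and the small peritoneal macrophage markers went both ways, with Plac8 up by 4.72 (SE 0.79) and Retnla down (-1.14, SE 0.43). The lipid and sterol list had 1 of 2 genes higher and 1 lower, the large peritoneal list and the neutrophil list 1 of 2 lower, the macrophage identity list 1 of 3 lower, and Ccr3, the 1 mast cell, eosinophil and basophil marker, fell (-1.63). In the cell cycle and progenitor lists edgeR called 0 of 2 and 0 of 1 genes, with 1 and 0 at an unadjusted p under 0.05. With edgeR's quasi-likelihood test on 2 against 2 annotated replicates, 104 of 418 genes rose and 76 fell (Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold). List counts adjusted over the list alone were the same, except that in the alternative activation list 2 rose and 0 fell. The replicates were not said to be separate cultures, so p may measure technical spread. The split depended on scaling: 126 rose and 39 fell in counts per cell, 88 rose and 104 fell with library totals, and the median of all genes moved from -0.15 to 0.25 and -0.46.

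Polarization with interleukin 4 raised genes of alternative activation. In untreated M2 cells the membrane protein gene Tmem26 rose by 6.40 (SE 0.31, adjusted p = 3.14e-07), the Ras activator Rasgrp1 by 6.03 (SE 0.77), the chitinase-like gene Chil3 by 5.95 (SE 0.69), the secreted factor Retnla by 5.46 (SE 0.34), the arginine-degrading enzyme Arg1 by 5.44 (SE 0.13), the arginine transporter Slc7a2 by 5.15 (SE 0.12), the integrin Itgb8 by 4.65 and the adaptor Scimp by 4.64. Of 13 measured members of the alternative activation list 10 rose and 0 fell. The transcription factor Irf4 (4.50, SE 0.23) rose in the small peritoneal macrophage list, where 2 of 3 genes rose, and Socs1 (4.33, SE 0.32) was the 1 of 12 interferon gamma genes that rose, while 1 fell. In M0 cells of this library, 53.9% of Arg1 UMIs lay in 34 of 2968 cells, and Retnla and Chil3 stood at 2.17% and 1.54% of their M2 level per cell.

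Among the genes lower in M2 cells, the early growth response gene Egr3 fell by 5.18 (SE 0.61), the matrix protein Thbs1 by 4.76 (SE 0.27), Marcksl1 by 4.33, the formyl peptide receptor Fpr1 by 4.23 and Cd14 by 3.83 (SE 0.08). Of 25 early NF-kB genes 5 fell and 1 rose, led by the chemokines Ccl3 (-2.32, SE 0.11) and Ccl4 (-2.13, SE 0.08), and Tnf fell by 1.02 (SE 0.08). Of 17 type I interferon genes 6 fell, among them Ifit1 (-1.56, SE 0.54), and 2 rose (Ccl12, 1.65, and Mx1, 1.61); Cxcl10 (-1.06, SE 0.30) and Ccl5 (-1.83, SE 0.60) fell. Of 12 immediate-early genes 4 fell (Fosb -3.94, Nr4a1 -3.54, Fos -1.32) and 1 rose. Late cytokine genes were mixed with 5 of 16 higher (Csf1, 1.82, and Ccl7, 1.14) and 3 lower, feedback regulators had 2 of 11 higher (Dusp2, 1.41, and Dusp4, 1.05) and 1 lower, and oxidative stress genes had Slc7a11 higher (1.38) and Egln3 lower (-1.31). The lipid list had 1 of 2 genes higher, the macrophage identity list 1 of 3 and the large peritoneal list 1 of 2 lower, and Ccr3 fell (-1.03). edgeR called 0 of 2 neutrophil, 0 of 2 cell cycle and 0 of 1 progenitor genes, with 1, 2 and 1 at an unadjusted p under 0.05. In all, 84 of 418 genes rose and 72 fell, and each list's counts were the same when adjusted over the list alone. Under library totals 70 rose and 89 fell, and under counts per cell 91 rose and 61 fell. Il1b (-0.49, SE 0.47) and Nfkbia (0.17, SE 0.41) did not pass.

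**Figure D1:**
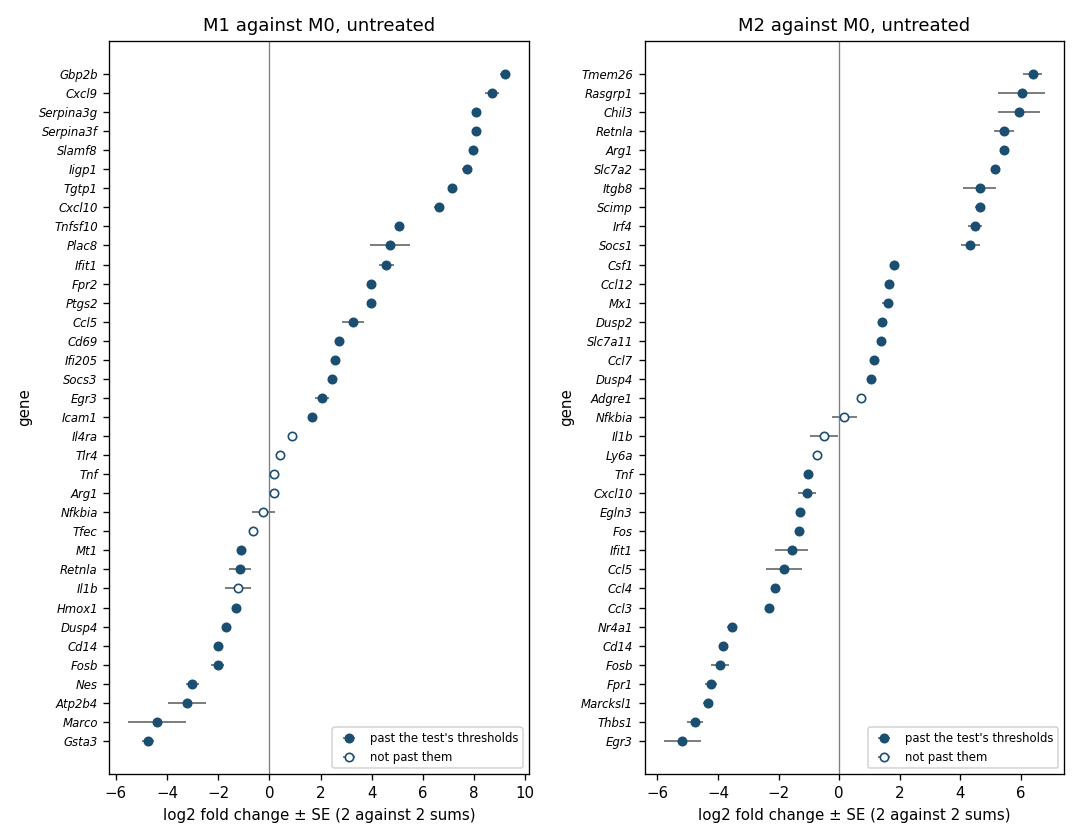
Log2 fold changes (x axis) of genes chosen by the rule for named genes, not all of them shown (y axis) in untreated M1 (left) and M2 (right) cells against untreated M0 cells, with edgeR's standard errors, 2 sums against 2. Filled points passed the thresholds, from Gbp2b at 9.21 to Gsta3 at -4.75 in M1 cells and from Tmem26 at 6.40 to Egr3 at -5.18 in M2 cells, and Ifnb1, with 0 UMIs in M0 cells, is left out.

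The next question was how M0 cells at 3 h after each ligand differed from untreated cells. Untreated M0 cells were 0 h samples, so ligand and time in culture are not separated here. In libraries 8 and 12, cytokine and interferon genes were far above the untreated cells of library 3. After LPS in library 8 the chemokine Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand) was higher by 11.07 on the log2 scale (95% interval 10.80 to 11.37), the cytokine Il6 (chromosome 5, 30013114 to 30019981, plus strand) by 11.07 (10.32 to 12.08), Tnf (chromosome 17, 35199381 to 35202007, minus strand) by 5.39 (5.32 to 5.46), Il1b by 7.95 (7.70 to 8.23) and the interferon-induced Ifit1 by 8.89 (8.25 to 9.71). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254, plus strand), and Ifnb1 had 0 UMIs in those untreated cells and were higher by at least 9.23 and 10.03. The interleukin 12 subunit gene Il12b, with 1 UMI there, was higher by 12.83 (10.94 to 18.72). In library 12 Cxcl10 was higher by 11.11, Il6 by 10.83 and Tnf by 5.39 after LPS, and Cxcl10 by 9.16 and Tnf by 5.47 at the lower LPS dose. Among the lower genes after LPS in library 8 were the phosphatase gene Dusp6 (-7.97), Fos (-5.14), the glutathione synthesis gene Gclm (-4.30) and Arg1 (chromosome 10, 24915221 to 24927484, minus strand, -10.38), whose untreated level lay in a cartridge that held mostly M2 cells.

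Early NF-kB and interferon genes were set side by side for each ligand in M0 cells of library 8. After P3CSK, CpG and TNF the early NF-kB list had medians of 3.72, 3.55 and 3.60 and the type I interferon list 1.33, 1.30 and 2.06. After LPS these medians were 3.11 and 5.60, after PIC 2.21 and 5.38 (4.83 with genes at 0 UMIs set to their bound), and after IFNb -0.47 (1.86 in counts per cell and 0.41 with TMM factors) and 6.73. The late cytokine medians were 4.00, 3.82, 3.05, 3.16, 2.40 and 0.53 for P3CSK, CpG, TNF, LPS, PIC and IFNb. Tnf was higher by 6.07 (6.00 to 6.14) after P3CSK, 5.98 (5.92 to 6.05) after CpG, 3.68 after TNF and 2.96 after PIC, and stood at -0.05 (-0.12 to 0.03) after IFNb, which was 2.28 in counts per cell. Cxcl10 was higher by 10.90 after IFNb and 10.36 after PIC, with 5.59 to 6.17 after TNF, P3CSK and CpG. IFNb cells also had Ifit1bl1 higher by 12.78, Ifit3 by 8.19, the antiviral GTPase Mx2 by 8.00 and the antiviral enzyme Rsad2 by 7.66. In library 12 the early NF-kB and interferon medians were 2.72 and 4.97 after LPS, 3.19 and 2.47 after P3CSK and 3.06 and 2.76 at the lower LPS dose. Immediate-early and oxidative stress genes had medians of -2.65 and -2.01 after LPS in library 8, which were 0.62 and 1.26 in counts per cell. Scaling mattered for falls in all comparisons across depths: in counts per cell the median of all genes moved from -0.24 to 3.03 for LPS in library 8.

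In library 13 the ratios were smaller, and the untreated cells used as its reference were themselves high in these genes. Against them, LPS gave 0.13 for the early NF-kB list, 0.54 for the late list and 0.60 for the interferon list, PIC gave -0.18, -0.60 and 1.07, CpG gave 0.78, 0.38 and -1.17, and TNF gave 0.53, -0.36 and -0.57. In counts per cell the early NF-kB median after PIC was 0.42, and the late medians after PIC and TNF were above 0. Cxcl10 was higher by 0.96 after LPS and 1.25 after PIC and lower after CpG (-1.34), while the acute phase gene Saa3 (2.17) and the chemokine Cxcl2 (2.02) were higher after CpG and Vcam1 (2.50) and Ccl22 (2.22) after TNF. The untreated cells of library 13 exceeded those of library 3 by 9.95 (9.67 to 10.25) in Cxcl10, 9.56 (8.82 to 10.58) in Il6, 7.30 in Il1b and 4.82 in Tnf, and by 5.61 in the median of the interferon list. They numbered 1004, with a median of 323.5 UMIs.

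Across libraries, edgeR's quasi-likelihood test called 0 of 481 genes for each ligand against untreated M0 cells. The counts at an unadjusted p under 0.05 were 114 for LPS, 98 for CpG, 90 for P3CSK, 50 for TNF and 30 for PIC, and the LPS fold changes included Ifit1 at 3.97 (SE 1.58, adjusted p = 0.156) and Nos2 at 8.52 (SE 2.95, adjusted p = 0.117). The same test called 0% of simulated 4-fold changes, so this says nothing of the absence of a response. Libraries deviated together, and with the library as a block 49 genes rose and 40 fell after LPS, 14 and 11 after CpG, 0 and 3 after PIC, and 0 and 1 after TNF and after P3CSK. In that fit 6 of 18 interferon genes rose after LPS, 18 when adjusted over the list alone, and 5 of 27 early NF-kB genes rose. After CpG 2 of 27 early NF-kB genes rose, 18 over the list alone, and after P3CSK 0 rose, 13 over the list alone. DESeq2 called 108 genes for LPS, 71 for CpG, 76 for P3CSK, 18 for TNF and 3 for PIC, and without library 13 edgeR called 152 for LPS, 50 for CpG, 72 for P3CSK, 13 for PIC and 0 for TNF. In that fit untreated cells, CpG, PIC and TNF had 1 sum each, assumed to vary like LPS and P3CSK between libraries 8 and 12, and untreated cells were in another cartridge than every ligand. The blocked comparisons of LPS, CpG, PIC and TNF with untreated cells rest on library 13, the 1 library that holds both, and that of P3CSK, which no library holds beside untreated cells, is indirect, through the ligands that libraries 8 and 12 share with library 13. IFNb was present in 1 library and was not tested, as the plan asked for sums from at least 2.

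**Figure D2:**
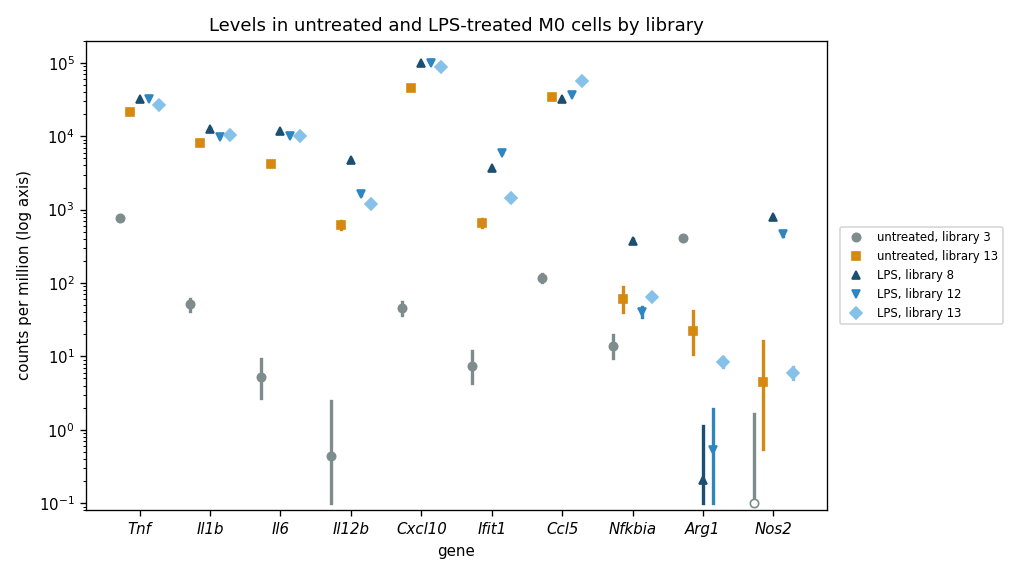
CPM (log axis) of 10 genes (x axis) in untreated M0 cells of libraries 3 and 13 and in LPS-treated M0 cells of libraries 8, 12 and 13, as points with exact Poisson intervals; the open point marks 0 UMIs, and intervals reaching 0 are drawn to the axis floor. For Cxcl10, Il6, Tnf and Il1b the untreated cells of library 13 lie near the LPS-treated cells and above the untreated cells of library 3.

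Pairs of ligands were compared within libraries to ask how far responses that share a pathway branch part. LPS exceeded TNF in interferon genes and cytokines in libraries 8 and 13: Il6 by 8.53 and 2.54, Il12b by 6.85 and 1.85, Cxcl10 by 5.49 and 1.60 and Ifit1 by 4.78 and 1.70. LPS exceeded CpG in Cxcl10 (4.91 and 2.31), Ifit1 (5.13 and 2.20) and Oasl1 (6.52 and 2.45), and lay below it in Tnf (-0.59 and -0.90), Il1b (-0.87 and -1.25) and the transcription factor gene Myc (-3.89 and -2.92). In counts per cell Tnf and Il1b of library 8 turned to 0.45 and 0.17, and those of library 13 stood at -0.27 and -0.62. LPS exceeded PIC in Il6 (6.34 and 2.47), Nos2 (6.24 and 1.78), Il1b (3.67 and 1.31) and Tnf (2.43 and 0.94), with Cxcl10 at 0.71 and -0.29. PIC against IFNb, both in library 8, gave higher Ifnb1 (6.48, 6.11 to 6.90), Ccl5 (5.48), Traf1 (5.43), Tlr2 (5.35) and Tnf (3.01), lower Serpina3f (-5.97), Serpina3g (-5.31) and Iigp1 (-4.87), and list medians of 2.53 for early NF-kB and -1.69 for type I interferon genes.

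Without a library term edgeR called 0 of 481 genes for LPS against TNF, CpG and PIC, with 53, 41 and 37 at an unadjusted p under 0.05, and DESeq2 called 25, 21 and 15. With the library as a block, which uses the within-library differences, 104 genes rose and 85 fell for LPS against TNF, 69 rose and 81 fell against CpG, and 72 rose and 81 fell against PIC. In the blocked fit 18 of 18 interferon genes rose against TNF and against CpG, the same counts over the list alone, with Ifit1 at 4.05 (SE 0.77, adjusted p = 0.007) and 4.03 (SE 0.76, adjusted p = 0.007) and Cxcl10 at 4.27 (SE 0.87) and 4.11 (SE 0.84). Against PIC 0 of 18 interferon genes were called, 0 also over the list alone, with Ifit1 at 0.66 (adjusted p = 0.456), while 15 of 25 late cytokine genes rose (16 over the list alone) and 13 of 27 early NF-kB genes rose, with Tnf at 2.22 (SE 0.52, adjusted p = 0.021) and Nos2 at 4.44 (SE 1.23, adjusted p = 0.029). The interferon medians against PIC in libraries 8 and 13 were 0.24 and -0.29 in CPM and 1.02 and 0.04 with TMM factors. In counts per cell they were 2.29 and 0.48, so 0 calls does not show equal interferon responses. Oxidative stress genes fell against each partner, 5 of 8 for TNF and PIC and 4 of 8 for CpG, with the same counts over the list alone. The size of these falls depended on scaling. In libraries 8 and 13 the list medians in CPM were -2.57 and -1.61 against TNF, -1.56 and -1.02 against CpG and -2.33 and -0.89 against PIC. In counts per cell they were -0.63 and -0.63, -0.52 and -0.39, and -0.28 and -0.13. These calls rest on 2 libraries that hold both ligands, and TNF cells of library 13 held Cxcl10 more often than those of library 8.

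M1 cells were compared with untreated M1 cells to ask how the polarized state responded. After LPS Il12b was higher by 10.15 (8.62 to 13.52), Il1b by 9.10 (8.68 to 9.58), the chemokine Ccl22 by 9.11, Il6 by 7.37 (6.62 to 8.38), Nos2 by 7.28 (6.20 to 9.04), Ccl5 by 6.28 and Tnf by 4.35 (4.28 to 4.42). Gclm (-5.65), Hmox1 (-5.28), Fos (-5.52) and the serotonin receptor Htr2b (-8.74) were lower. The early NF-kB median was 2.71 after LPS, 2.97 after CpG, 2.15 after P3CSK, 1.93 after TNF, 1.50 after PIC and -0.58 after IFNb (0.29 in counts per cell). The interferon median was 2.80 after IFNb, 1.93 after PIC and 1.36 after LPS, and lay between -0.46 and 0.08 after P3CSK, CpG and TNF, where counts per cell gave 0.82, 1.55 and 1.08. Cxcl10 was higher after each ligand, by 4.35 to 5.17, with 4.43 (4.40 to 4.46) after TNF and 4.69 after IFNb. The dendritic cell list, with Ccl22 and Fscn1, had medians of 1.89 after PIC to 5.34 after LPS with genes at 0 UMIs set to their bound. It has 3 genes, of which 1 was lower in CPM after PIC, LPS, P3CSK and TNF, and Ccl22 is also in the late cytokine list. These cells and their untreated reference were in different cartridges. For IFNb the interferon median lay below the 6.73 of M0 library 8, and the difference was not tested. Untreated M1 cells already held more RNA of most interferon genes, so a lower ratio need not mean a lower level. Cxcl10 stood 6.32 higher on the log2 scale in untreated M1 than M0 cells. After IFNb it stood at 16.51 log2 CPM in M1 cells and 16.40 in M0 cells of library 8.

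M2 cells answered LPS and PIC with interferon and chemokine genes. After LPS Ifnb1 was higher by 11.89, Cxcl10 by 11.79 (11.42 to 12.22), Il6 by 10.90 (9.82 to 12.66), Ccl5 by 10.27, Ifit1 by 9.95, Il1b by 7.04 and Tnf by 6.38 (6.28 to 6.47), and after PIC Cxcl10 by 12.13 and Ifnb1 by 12.26. The early NF-kB medians were 3.90 after LPS, 3.96 after CpG, 2.13 after PIC and after TNF, 2.10 after P3CSK and -0.87 after IFNb (1.10 in counts per cell). The interferon medians were 6.90 after IFNb, 6.05 after PIC (5.48 at the bound), 5.67 after LPS (5.23 at the bound) and 3.36 to 3.91 after P3CSK, TNF and CpG. Il12b was higher by 5.99 (5.14 to 7.20) after LPS but by 0.60 (-1.39 to 2.27), 0.54 (-1.45 to 2.21) and 0.03 (-1.65 to 1.60) after P3CSK, TNF and CpG. Arg1 was lower after each of the 6 ligands, from -1.51 after P3CSK to -3.43 (-3.46 to -3.40) after LPS. In counts per cell Arg1 stayed lower, at -0.60 to -0.90. The reference cells were in another cartridge, one with no 3 h cells of any ligand, and free RNA in either was not measured.

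**Figure D3:**
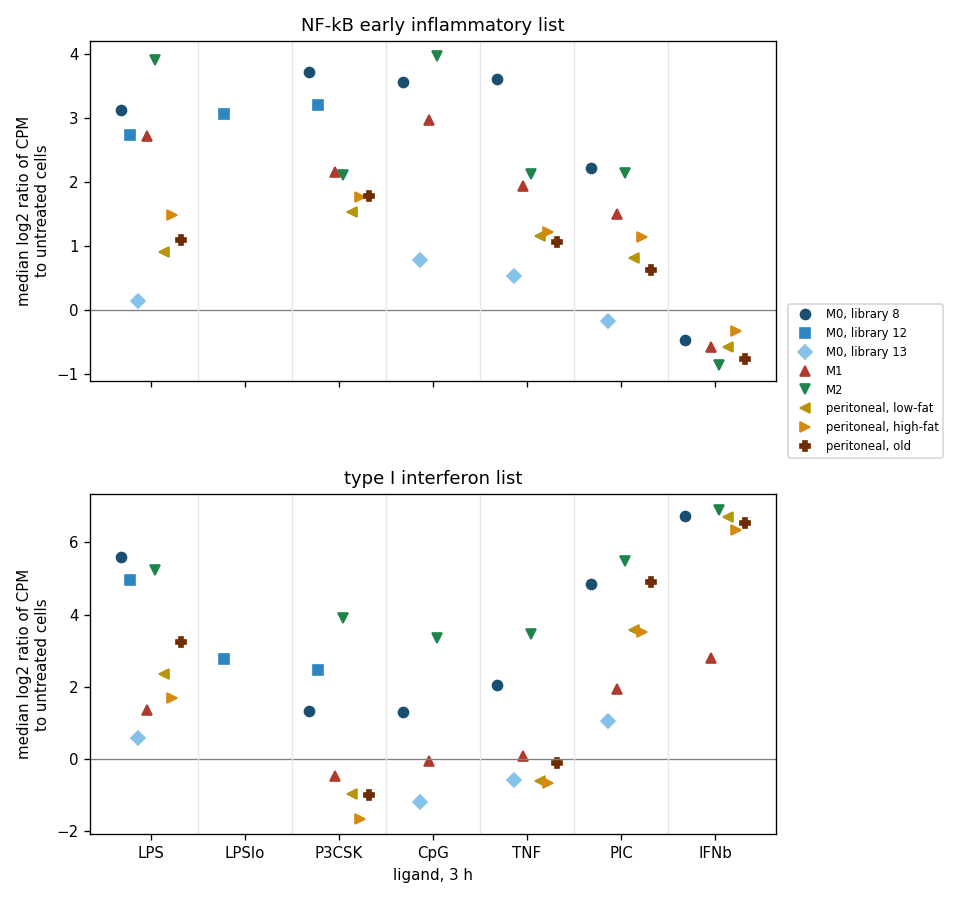
Median log2 ratio of CPM to untreated cells of the same kind (y axis) for the early NF-kB list (top) and the type I interferon list (bottom) by ligand at 3 h (x axis), 1 point per library and kind of cell, genes at 0 UMIs set to their bound. Untreated M0, M1 and M2 cells were 0 h samples and untreated peritoneal cells 3 h samples. Untreated M1 cells already held more RNA of most interferon genes than untreated M0 cells. After IFNb the interferon medians are 6.73 in M0, 2.80 in M1 and 6.90 in M2 cells while the early NF-kB medians lie below 0 in CPM, but at 1.86, 0.29 and 1.10 in counts per cell, and the points of M0 library 13 are taken against its own untreated cells.

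Times of 1 h, 3 h and 5 h were set side by side in M2 and M0 cells. In M2 cells at 1 h, within the cartridge of their untreated cells, the early NF-kB median was 3.23 after LPS, 2.89 after P3CSK, 2.43 after TNF and 2.32 after CpG, against 0.11 after PIC and 0.12 after IFNb. The interferon median at 1 h was 3.59 after IFNb, 0.02 after PIC and -1.03 after LPS (0.04 in counts per cell). At 5 h it was 7.47 after IFNb, 7.40 after PIC (6.64 at the bound) and 6.94 after LPS (6.19 at the bound). Immediate-early genes had a median of 1.60 after LPS at 1 h and -1.35 at 3 h (1.30 in counts per cell). In M0 cells at 1 h the early NF-kB median was 3.39 after P3CSK, 3.16 after LPS, 3.04 after CpG, 2.56 after TNF and 1.79 after PIC, and the interferon median 5.22 after IFNb, 2.67 after PIC and 1.10 after LPS. At 5 h after LPS the late cytokine median was 5.55 in M0 and 3.36 in M2 cells. M2 cells were in library 3 at 1 h and library 1 at 3 h and 5 h, and M0 cells in library 8 at 1 h and library 12 at 5 h, against untreated cells of library 3, so times were in part in different cartridges. Within each kind of cell no ligand was in more than 1 library at 1 h or 5 h, nor in M2 cells at 3 h.

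Peritoneal macrophages were compared with untreated cells of their own cartridge, which were also 3 h samples. After LPS Il1b was higher by 5.92, 6.20 and 5.84 in low-fat, high-fat and old cells, Il6 by 5.66, 6.33 and 5.69, the chemokine Ccl4 by 5.78, 5.40 and 5.88, Tnf by 4.51, 4.64 and 3.80 and Cxcl10 by 5.25, 4.07 and 5.34. The transcription factor gene Hhex (-7.00, -6.70 and -6.31), Irf8 (-5.00, -4.57 and -3.66) and the macrophage marker Adgre1 (-2.36, -2.37 and -2.38) were lower in CPM. In counts per cell Hhex and Irf8 remained lower while Adgre1 stood at -0.03, 0.01 and -0.15. After IFNb the interferon medians were 6.69, 6.51 (6.33 at the bound) and 6.52, with Ifit2 higher by 8.70, 8.97 and 9.44. After PIC they were 4.46, 3.78 and 4.90 (3.58 and 3.53 at the bound in the low-fat and high-fat arms), and after LPS, at the bound, 2.36, 1.69 and 3.24. After P3CSK the early NF-kB medians were 1.53, 1.88 and 1.78 with Cxcl3 higher by 5.94, 6.13 and 5.37, and the interferon medians were -0.97, -1.62 and -0.99, which in counts per cell were above 0 in the low-fat (0.29) and old (0.27) cells. TNF gave early NF-kB medians of 1.15, 1.23 and 1.06 with Acod1, the itaconate-producing enzyme, higher by 3.60, 3.99 and 3.22. The neutrophil marker S100a8 was seen in 68.2% to 85.9% of peritoneal cells in every sample, untreated ones included and without thinning, against 0.763% to 1.89% of M1 cells at 3 h, 11.3% to 17.2% of untreated cells of library 3 and 24.1% to 27.6% of M0 cells of library 12. In library 12, 15.7% to 23.0% of M0 cells held at least 2 different markers of other cell types. The panel held 3 such markers, S100a8, Mmp8 and Ccr3, and Ccr3 was found in 63.4% to 71.7% of these M0 cells. Holding 2 markers therefore does not by itself mark a cell of another type. The high-fat untreated sample of 58 cells held 3 UMIs of Ifit1 and 3 of Il12b, which limits its ratios.

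High-fat and low-fat cells were then compared within their cartridge, ligand by ligand. Chil3 was lower in the high-fat arm in all 6 samples, from -3.08 after PIC to -3.64 after P3CSK, with -3.42 (-3.85 to -3.03) in untreated cells and -3.22 (-3.33 to -3.11) after LPS. The gelatinase gene Mmp9 was higher after PIC (2.13), LPS (2.45), P3CSK (3.04) and TNF (2.49), as was Ahrr, the repressor of the aryl hydrocarbon receptor (2.58, 3.44, 3.12 and 2.35). Retnla was higher after PIC (1.98), P3CSK (2.77) and TNF (1.86), and Arg1 was lower in untreated cells (-1.72, -2.18 to -1.32). Retnla is in the small peritoneal macrophage list, whose 3 genes were all higher after PIC, P3CSK and TNF (medians 1.98, 2.72 and 1.42). After LPS and IFNb 2 of these genes were higher and 1 lower (medians 0.73 and 0.89). Cxcl10 was lower in the high-fat arm after PIC (-0.95, -0.98 to -0.92) and LPS (-0.86, -0.88 to -0.84) and higher after IFNb (0.31), and Tnf was higher after PIC (0.62) and lower after LPS (-0.27). The interferon median was 0.34 in untreated cells (percentile 69.5 of random lists, 0.04 in counts per cell and 0.12 with TMM factors), -0.52 after PIC, -0.26 after LPS, -0.25 after P3CSK, 0.06 after TNF (-0.12 in counts per cell and -0.13 with TMM factors) and 0.28 after IFNb. Cells with at least 2 different markers of other cell types made up a higher share of high-fat than of low-fat cells in all 6 samples, with 6.90% against 2.16% untreated, 13.1% against 3.18% after LPS, 8.07% against 2.52% after P3CSK, 6.19% against 1.50% after TNF, 4.69% against 2.36% after PIC and 2.83% against 1.38% after IFNb. S100a8 and Mmp8 were each found in a higher share of high-fat cells in all 6 samples. Most cells of both arms held S100a8, so the marker count does not by itself show other cell types. Diet was represented by 1 tag per ligand and arm, so differences between mice cannot be separated from it.

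Old cells were in another cartridge, so responses to each cartridge's own untreated cells were compared with those of the low-fat arm. Over the genes of the interferon list the median difference in response was 0.87 after PIC, 0.80 after LPS, 0.56 after TNF, 0.11 after P3CSK and 0.18 after IFNb. Over the interferon gamma list it was 0.82, 0.67, 0.55, 0.72 and 0.05. With TMM factors the interferon values were 0.59, 0.28, 0.31, -0.28 and 0.14 and the interferon gamma values 0.54, 0.16, 0.30, 0.33 and 0.01. Among single genes the plasminogen activator Plat had a higher response in old cells after LPS (4.52, 3.74 to 5.30), P3CSK (5.15, 4.36 to 5.93) and TNF (5.24), the cholesterol hydroxylase Ch25h after LPS (3.34, 2.83 to 3.85), TNF (4.15) and IFNb (3.16), and the protease inhibitor Timp1 after LPS (3.60) and P3CSK (3.45). Vcam1 (3.32 after LPS) and Ptgs2 (2.09) also had a higher response. These differences may rest on the 232 untreated low-fat cells, where Plat, Ch25h, Timp1, Vcam1 and Ptgs2 stood at 737, 255, 2550, 466 and 1307 CPM against 11.3, 48.4, 197, 51.6 and 416 in untreated old cells, while after LPS Timp1 stood at 594 CPM in low-fat and 558 in old cells and Plat at 179 and 64.9. For Timp1 and Plat after LPS the level itself was not higher in old cells, so their higher response comes from the untreated levels. The responses of the chemokine Cxcl1 (-1.44, -1.64 to -1.23) and Tnf (-0.71, -0.83 to -0.59) to LPS were lower. Cxcl10 differed by 0.69 (0.35 to 1.02) after PIC and 0.09 (-0.25 to 0.43) after LPS. Age, diet and cartridge could not be told apart.

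Single cells were assigned to their ligand to ask how separable the samples of each ligand were. Within a library each ligand was 1 tagged sample per kind of cell, or 2 for LPS in library 13. Differences between ligands and between samples are therefore not separated, and the intervals treat cells as independent. Among LPS, PIC and TNF, 94.9% of M0 cells in library 8 and 84.4% in library 13 were assigned to their own ligand (89.7% ± 7.43, SD, n = 2 libraries), against 94.2% in M1, 93.9% in M2, 92.4% in low-fat, 87.3% in high-fat and 95.8% in old cells, with chance at 33.3%. Trained on library 8 and applied to library 13 the share was 59.6% (exact binomial 95% interval 57.2 to 61.9), and in the other direction 63.2% (60.9 to 65.5). With all 6 ligands in library 8 the share was 82.7%, with IFNb cells at 99.8% and LPS cells at 98.3%. CpG and P3CSK cells were taken for each other: 62.0% of CpG cells were assigned to CpG and 35.0% to P3CSK, and 61.5% of P3CSK cells to P3CSK and 36.1% to CpG. The 6-ligand share in M1 cells was 81.9%, and the 95% interval of that in M2 cells ran from 78.5% to 81.3%. A random forest in place of the regression gave 54.5% and 74.0% across libraries. After thinning, 15.2% of TNF cells of library 13 held no Cxcl10, against 67.7% of those of library 8. For LPS cells these values were 0.508% and 0.151%. Library 13 also held 51264 barcodes, more than the number loaded per the labels. The lower shares across libraries therefore do not by themselves show that responses to a ligand differ between M0 libraries.

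**Figure D4:**
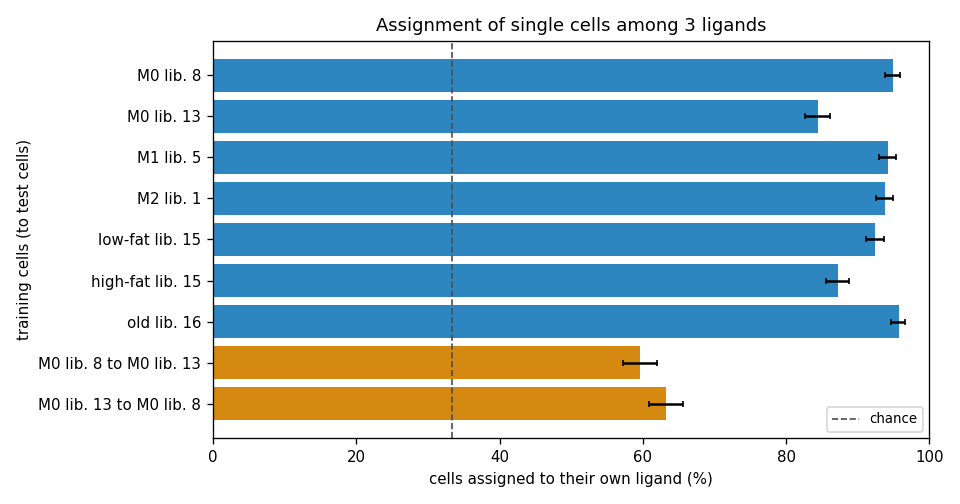
Percent of cells assigned to their own ligand among LPS, PIC and TNF (x axis) by library and kind of cell (y axis), as bars with exact binomial 95% intervals; the dashed line is chance at 33.3%. Blue bars are held-out cells of the same library, from 84.4% to 95.8%, and orange bars are trained on 1 M0 library and applied to the other, at 59.6% and 63.2%. Each ligand was 1 tagged sample per library and kind of cell, or 2 for LPS in library 13, and intervals treat cells as independent. The TNF cells of the 2 M0 libraries differed in the share that held Cxcl10. The orange bars therefore do not by themselves show that responses to a ligand differ between these libraries.

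The share of cells with at least 1 UMI, after thinning each cell to 300 UMIs, differed by gene and kind of cell. After LPS Cxcl10 was found in 99.1% ± 1.05 of M0 cells (SD, n = 3 libraries; 99.7% not thinned), 99.8% of M1 and 95.4% of M2 cells, against 1.07% of untreated M0 cells in library 3 and 90.2% in library 13. In peritoneal cells after LPS it was found in 54.9% of low-fat, 34.6% of high-fat and 69.5% of old cells (85.0%, 63.8% and 86.7% not thinned), against 6.03%, 8.62% and 11.8% of untreated cells. Il6 was found after LPS in 65.1% ± 4.58 of M0 cells (n = 3 libraries; 87.3% not thinned), 12.3% of M1 cells (38.8% not thinned) and 30.6% of M2 cells (67.6%), and in 31.9% of untreated cells of library 13. Nos2 was found after LPS in 15.4% and 10.9% of M0 cells in libraries 8 and 12, 0.173% in library 13 and 8.24% of M1 cells, against 0 of 2906 thinned untreated M0 cells of library 3, which allows up to 0.103% of cells with a UMI at this depth and sets no limit to cells expressing the gene. Median depths after LPS were 6630 UMIs per cell in library 8, 5995.5 in library 12, 1007 in library 13, 4374 in M1 cells and 5480.5 in M2 cells, and untreated cells of libraries 3 and 13 had 683 and 323.5. Cells under 300 UMIs, left out of thinning, numbered 0 in library 8, 1 in library 12 and 493 of 16641 in library 13 after LPS, and 62 of 2968 and 465 of 1004 among the untreated M0 cells of libraries 3 and 13.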

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

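The comparison of M1 cells at 5 h was not planned, and its tests of lists were chosen after the 3 h result was seen. Against untreated M1 cells of another cartridge the early NF-kB list had a median log2 ratio of 1.04 after PIC, 1.86 after LPS, 2.08 after P3CSK, 1.72 after TNF and 3.07 after CpG, above the level of the untreated cells. The type I interferon list had a median of 2.94 after IFNb. The corresponding medians at 3 h over the same genes were 1.50 after PIC, 2.71 after LPS, 2.12 after P3CSK, 1.93 after TNF, 2.97 after CpG and 2.80 for the interferon list after IFNb. The 8 libraries used hold no replicate of M1 cells at 5 h, and the differences between times were not tested.

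No group held between 4 and 10 samples, so no sample was tested for standing apart from its group. For each ligand the 10 genes named in every comparison were also checked between M1 and M2, low-fat and high-fat, and low-fat and old cells. With at least 50 UMIs behind each response, for 0 of them did both reach 1 on the log2 scale in opposite directions. Below that number of UMIs, Il12b after IFNb was 3.58 in M1 cells (14 against 2 UMIs) and -3.28 in M2 cells (1 against 9 UMIs).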

How the results depend on the processing

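The sums of untreated replicates, the block by annotated replicate number, most settings of the polarization tests and the choice of list medians for the untested comparisons were chosen only after the result was seen. The M0 counts of called genes, each 0 in the main test, depended on the settings. With the library as a block, which rests on the pairing of sums within libraries, 89 genes were called for LPS, 1 for TNF, 3 for PIC, 25 for CpG and 1 for P3CSK against untreated cells, and 189, 150 and 153 for LPS against TNF, CpG and PIC. The DESeq2 Wald test called 108, 18, 3, 71 and 76, and 25, 21 and 15. DESeq2 size factors gave 8 for LPS and library totals 19. Separate sums of the untreated replicates gave 76 for LPS, 27 for CpG and 36 for P3CSK, and a block by annotated replicate number gave 172, 77 and 67, and 2 for LPS against TNF. Leaving out each library in turn gave 0 to 152 for LPS, 0 to 13 for PIC, 0 to 50 for CpG, 0 to 72 for P3CSK and 0 to 1 for LPS against TNF, the highest each time without library 13, and each such fit leaves some groups with 1 sum, assumed to vary like the others. Counts per cell, no filter and cells of at least the thinning depth left all 8 counts at 0. The cause was not tested. For IFNb, present in 1 library, the blocked, DESeq2, unfiltered and leave-out fits were not run, although the spread of the other groups would allow them.

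The M1 and M2 counts of 180 and 156 stayed within 149 to 192 in every setting, and 143 and 145 of these genes were also called in counts per cell, 164 and 142 with library totals, 175 and 155 with a block by annotated replicate number, and 159 to 170 and 139 to 143 with single replicates left out. Without M1 replicate 2 the called gene Serpinb2, named after its values were seen, went from 4.42 (SE 1.52, adjusted p = 0.0284) to -2.42 (SE 0.75, adjusted p = 0.0257). Small fold changes that had not passed also changed sign. Under library totals Tnf in M1 was -0.14, Arg1 in M1 -0.15 and Nfkbia in M2 -0.023, and in counts per cell Nfkbia in M1 was 0.14. With single replicates left out Nfkbia in M1 ran from -0.74 to 0.59, Arg1 in M1 from -0.037 to 0.37, Il1b in M2 from -1.08 to 0.35 and Nfkbia in M2 from -0.34 to 0.99, the lone replicate being assumed to vary like the other groups. Each of these comes from scaling or from a single replicate by construction.

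List medians without a test moved with scaling by differing amounts, and no counting interval was computed for them. In counts per cell the interferon list after IFNb was 9.06 in M0, 3.67 in M1 and 8.86 in M2 cells, the early NF-kB list after LPS 4.76 in M1, 6.55 in M2 and 3.23 in low-fat cells, and PIC against IFNb 1.41. The high-fat differences of the interferon list were -0.51 after LPS and -0.88 after PIC. With TMM factors the interferon list after IFNb was 7.61 in M0, 3.17 in M1, 7.63 in M2 and 7.30 in low-fat cells, the early NF-kB list after LPS 3.38, 4.05 and 2.21, PIC against IFNb 1.14, the high-fat differences -0.48 and -0.73, and the old difference after LPS 0.28. None of these medians changed sign, but others did: in counts per cell the early NF-kB list after IFNb was 1.86 in M0, 0.29 in M1 and 1.10 in M2 cells, and the interferon list after P3CSK in M1 cells 0.82, all below 0 in CPM. The share of M0 cells with Cxcl10 after LPS was 98.0% at 2 UMIs. Among shares of single samples 333 moved and 76 did not when cells were not thinned. Depth limits ratios against sums of few cells, such as the 58 untreated high-fat cells, and genes with few UMIs in untreated cells.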

Other observations

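The test of a single mixing share, the free RNA test over 45 genes, both tests of Cxcl10 in M1 cells and the free RNA test of Arg1, Retnla and Chil3 were chosen only after the result was seen, the test of several ligands after the Cxcl10 values of these cells were seen, and the deciding intervals for library 13 and for these 3 genes after point values that alone would have decided the tests. The tests of a mixing share and of Cxcl10 before the ligand replaced earlier ones that had pointed for the first and against the second, and the spread between libraries was added to the first after its value was seen.

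Some genes of the responses have not been described. In M2 cells TNF gave higher Traf1 (7.40), an adaptor of TNF receptors, and higher Ccl22 (6.49) and Ccl17 (6.32), chemokines of T cell recruitment, and IFNb gave higher Cd69 (7.62) with lower Egr2 (-5.89) and Irs2 (-6.15), the latter an adaptor of insulin and interleukin 4 signalling. In M1 cells IFNb gave lower Ccl7 (-4.35) and Cxcl2 (-4.67). In peritoneal cells IFNb gave higher Arg1, by 1.03, 2.75 and 1.07 in low-fat, high-fat and old cells. High-fat cells exceeded low-fat cells in the serpin Serpinb9b after PIC (3.74), LPS (3.33) and IFNb (4.26) and in the collagenase Mmp13 after PIC (2.45) and LPS (2.17), and untreated high-fat cells were lower in Timp1 (-5.68, -9.05 to -4.14, 2 UMIs) and higher in Ly6a (3.08). Untreated low-fat cells also stood above untreated old cells in Timp1, so its difference may rest on the low-fat sample and cannot be credited to the high-fat arm. None of these values has a replicate.

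Untreated M0 cells of library 13 held inflammatory and interferon RNA near the level of the stimulated cells beside them. A single share of the library's pooled RNA added to every gene cannot be told apart: over 45 induced genes the median share was 0.692 (quartiles 0.606 and 0.777, with Irf7 at 1.17 the 1 gene whose interval lay above 1), and the counting interval held the median in 37.8% of genes, but in 100.0% when the spread between libraries was added. Free RNA as the whole of it, taken up in like numbers by every cell, would make up a like or smaller share of deep cells. Uneven uptake could give a larger share, since depth counts these transcripts too, and was not tested. The share of UMIs in the 3 lists was 1.69 (1.59 to 1.81) times as high in the deepest as in the shallowest 25% of cells. This argues against free RNA taken up in like numbers. That share also rose in untreated cells of library 3 (1.61 times), a cartridge with stimulated M2 cells, but over the 45 genes it was 2.87% and 2.47% in the shallowest and deepest such cells there against 25.3% and 44.7% in library 13, and with the 2.47% taken off the ratio was 1.67 (1.58 to 1.78). Stimulated cells carrying the untreated tag may account for it, but neither 9.83% (7.45 to 12.7) of cells without Cxcl10, against 98.9% in library 3, nor 56.1% (50.1 to 62.0) of 278 cells with stimulated levels assigned to PIC decides, and activation in the well stays open and untested.

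In M1 cells Cxcl10 was as high after TNF (16.25 log2 CPM) as after IFNb (16.51), while in M0 cells of library 8 it stood at 11.09 and 16.40. Free RNA of the cartridge would have needed a share of 0.752 of the pooled profile, 8.06 times the highest limit that Il6, Il12b and Ifnb1 allow, which argues against it. A higher level before the ligand cannot be told apart: untreated M1 cells exceeded M0 cells by 6.32 on the log2 scale, 1.23 times the difference after TNF (5.16), so a ligand that multiplies the level would give it, while as an added amount the untreated level was 4.63% of that after TNF. Cartridge and polarization are confounded here, and a different response of M1 cells to TNF stays open and untested.

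Arg1, Retnla and Chil3 gave the largest falls of M0 and M1 cells after nearly every ligand against untreated cells of library 3, a cartridge that held mostly M2 cells. Untreated M0 cells held 0.312, 0.0964 and 0.0664 UMIs of these genes per cell, 2.22%, 2.17% and 1.54% of the M2 level, and those of library 13 held 0.00996 of Arg1 and 0 of the others. Free RNA of M2 cells would give M0 and M1 cells like numbers, and the largest log2 difference was 1.51 (0.09 to 3.95), so it cannot be told apart. M2 cells carrying an M0 tag may hold 53.9% (37.4 to 64.7) of the Arg1 UMIs, in 34 cells (1.15%), and this interval spans the 50% set in advance, so it cannot be told apart either. A true loss of these transcripts after stimulation stays open and untested.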
